A study of Mus musculus with 4 samples.

How the data were processed

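RNA of sorted airway smooth muscle cells from mouse lung was measured on 4 Affymetrix expression arrays, 1 each for VAS, VAD, CTR and BMS, with RNA of 3 mice pooled per array per the series' design text. The deposited values are on the log2 scale and were made by the authors with RMA, which corrects background, normalizes between arrays and summarises probes, using affy 1.36.1 in R 2.15.1 per the submitters' processing notes. Whether these 4 arrays were normalized alone or with others is not given in the sources used here. Quantile-type normalization gives every array nearly the same distribution, so a shift shared by most genes would not be visible. No scanner intensities were used, so background detection per probe set is unknown, and the number of arrays limits the precision. All 4 groups come from the sample titles, and the protocol text gives the diets.

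The table holds 25206 probe sets, each named by an Entrez gene number. In GEO's platform annotation, 23185 had 1 gene symbol, none had several and 2021 are unnamed here. All 23185 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez number, with 0 changed symbols and 0 symbols on more than 1 probe set. No genome was used, so positions are not given. Between 68 and 89 probe sets had the same value on a given pair of arrays, and no array was a copy of another.

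Genes were kept where the highest of the 4 values reached the median of all named values, 6.05, which left 12395 genes (53.5%). Each comparison is the difference of 2 log2 values, and genes at least 2-fold apart were counted in each direction, with the difference of the 2 controls counted the same way. These counts carry no test, since each group is 1 array. For each of 38 gene and marker lists, the median difference of the members past the filter was set among 10000 random lists of the same size, drawn from 20 bins of mean expression, and read as outside when beyond the middle 95% of them. These percentiles describe these arrays. The test, with more than 1 array per side, was limma (lmFit and eBayes) on VAD and BMS against VAS and CTR. It took the experiment as a block, with Benjamini-Hochberg adjustment over all genes past the filter. For the lists, camera was run with a preset correlation of 0.01 and with an estimated one. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.

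The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, in each experiment, the 12 largest differences in each direction, without provisional or copy-rich names (predicted genes, Riken clones, microRNAs, small RNAs, olfactory and vomeronasal receptors, immunoglobulin genes and names of Rn with a number). The last was written as a bare prefix and is read as Rn followed by a number, since a bare prefix would drop unrelated genes. It also names the 10 genes in each direction with the largest smaller-of-both difference of one sign, all measured retinoic acid response genes, the 2 reporter genes, and up to 4 members of each list by mean difference and up to 2 by the difference in each experiment. Genes outside this rule, such as Mir505 and some of the genes in the closing section, were chosen after their values were seen.

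The steps were tested on simulated data. For VAD against VAS, in 10 draws of 12395 genes, 8 to 17 of 25 genes raised 2-fold, 24 to 25 of 25 raised 4-fold and 25 of 25 raised 16-fold or 64-fold were found past 2-fold, while 45 to 60 of 12195 unchanged genes also stood 2-fold higher and 41 to 62 2-fold lower. Of 200 unchanged random lists, 7 to 15 fell outside the range. A list with 10 raised members among 30 reached percentiles from 74.1 to 100, so a median can miss a change in a minority of members. These draws used the second noise model below. For the joint limma fit on 12395 genes, the first simulation drew each gene's noise from the real residual variances, which have 1 degree of freedom. It recovered few changes, and a second noise model, with variances drawn from the prior that limma fitted, was added after that outcome. Over 10 draws of each, with 50 genes per size, the first model recovered 0 to 0 genes changed 2-fold, 0 to 20 changed 4-fold, 16 to 36 changed 16-fold and 23 to 40 changed 64-fold, with 0 unchanged genes called. The second recovered 6 to 35, 45 to 50, 49 to 50 and 50 to 50, with 5 to 24 unchanged genes called. Which model is nearer to the real noise cannot be settled with 1 residual degree of freedom, so a count of 0 calls in this fit is not read as absence of change.

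Alternatives were no filter, a filter at the 75th percentile (7.67), thresholds of 1.5-fold and 3-fold, quantile normalization again, cyclic loess, unnamed probe sets included, the other experiment's control, the mean of both controls as a shared control, other limma settings, leaving out each array (without the block), and unmatched random lists. Counts of genes outside the range of both controls, and without markers of other cell types, were added after the data were seen.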

Results

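Airway smooth muscle cells were sorted from the lungs of adult mice that carried 2 reporters, a green one driven by the smooth muscle actin promoter of Acta2 and a red one driven by the promoter of Cspg4, which marks pericytes and vascular smooth muscle. Cells that were green and not red were collected. RNA of 3 mice was pooled for each condition and run on 1 expression array, so the series holds 4 arrays. In the diet experiment, VAS mice ate a vitamin A-sufficient diet with 15 IU of vitamin A per gram and VAD mice a deficient diet with under 0.1 IU per gram. The protocol gives the length of the deficient diet as 5 days in one place and as 3 days in another. In the antagonist experiment, mice ate a powdered sufficient diet for 3 days, mixed with corn oil alone (CTR) or with BMS, an antagonist of all retinoic acid receptors, at 5 mcg per gram. The question was how airway smooth muscle gene expression depends on retinoic acid, the active form of vitamin A. With 1 pooled array per group there are no replicates within a group. Differences below therefore compare arrays, with no spread between mice to set them against, and "higher" and "lower" describe these arrays only. The 2 control arrays, VAS and CTR, were both vitamin A-sufficient, and their difference is set beside the others. They also differ in experiment, diet form, vehicle and pool of mice, so their difference is not a measure of noise within an experiment.

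Acta2 (Entrez gene 11475), the reporter gene of the sort, stood at 11.96, 12.12, 11.98 and 11.95 on the log2 scale in VAS, VAD, CTR and BMS, near the top of each array's range. The highest of the 25 fibroblast list members past the filter stood above it on every array, at 12.56, 12.42, 12.47 and 12.62. Cspg4 (Entrez gene 121021), the gene of the excluded reporter, stood at 7.71, 8.22, 8.08 and 7.98. These values lay above the upper quartile of every array, which ran from 7.605 to 7.634. The level of Acta2 therefore does not show that other cells were absent. The median of all probe sets was between 5.97 and 6.02 on every array. Across all probe sets the correlation between arrays was lowest for the 2 controls, with a Pearson r of 0.987, and highest for VAS and VAD, with 0.992. These correlations are across genes, which are not independent replicates.

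The first comparison asked what a vitamin A-deficient diet did, VAD against VAS. Il17b, a cytokine gene of the interleukin 17 family, was 3.13-fold higher in VAD (Entrez gene 56069, 6.46 in VAS and 8.11 in VAD). Dhrs3, which reduces retinaldehyde to retinol, was 1.04 higher on the log2 scale, and Aldh1a1, which makes retinoic acid from retinaldehyde, was 0.75 higher. Chrm2, the M2 muscarinic acetylcholine receptor, differed by -1.25, from 10.62 in VAS to 9.37 in VAD. In all, 29 genes were at least 2-fold higher and 52 at least 2-fold lower in VAD among the 12395 genes past the filter on low values. Against CTR in place of VAS, 174 were higher and 45 lower, and against the mean of both controls 49 and 28, so the balance turns with the control. The 2 control arrays were 2-fold apart for 252 genes, 40 higher and 212 lower in CTR, so more genes separated the controls than separated VAD from VAS. The controls come from different experiments, so this does not place the VAD differences within noise. Across genes, the SD of the differences was 0.38 between the controls, 0.27 for VAD and VAS and 0.31 for BMS and CTR. Simulated arrays, with noise drawn from the prior that limma fitted, put 45 to 60 unchanged genes past 2-fold upward and 41 to 62 downward, where 29 and 52 were seen. That prior was fitted to these same arrays and takes in any difference of VAD not shared with BMS. The simulated counts therefore do not show what noise alone would give. Of the 29 higher genes, 13 also stood 2-fold above CTR, and of the 52 lower genes, 11 also stood 2-fold below CTR.

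Among the other large differences in VAD, Pnp2 was 2.12 higher, Esm1, a proteoglycan gene of endothelial cells, 1.49, Trim67 1.40, Gzma, a granule protease of cytotoxic lymphocytes, 1.37, and Trim34a 1.33. Smoc2, a matrix-associated calcium-binding protein, was 1.29 higher, as were Tdo2 and the histidine decarboxylase gene Hdc, both with 1.29. Pappa2 was 1.24 higher, the leukocyte receptor gene Lilrb4a 1.20 and the macrophage gene Acod1 1.17. Trim67, Trim34a and Pappa2 were as high in CTR as in VAD, with CTR minus VAS values of 1.40, 1.24 and 1.22. The largest differences downward were Padi4 with -4.12 and Rpl31-ps21 with -4.00. Both were also low in CTR, with CTR minus VAS values of -4.08 and -4.19, so VAS was the array that stood apart. Whether all pools had the same strain background is not given in the sources used here, which bears on genes such as these 2 that lay below the array's median in some pools and far above it in another. It was not tested for any gene. Npm1 differed by -2.10 and was near its VAS level in both other arrays. Retnla, a secreted protein of alternatively activated macrophages, differed by -2.80, Hbb-b1, a beta globin gene, by -2.0, and Sftpc, surfactant protein C of alveolar type 2 cells, by -1.58. Each of these last 3 was also lower in CTR than in VAS, by -3.74, -1.93 and -3.54. Dpp4 differed by -1.69, Prss35 by -1.60, AW549542 by -1.57, Mrap2 by -1.50, the clock output gene Dbp by -1.47 and Abra, an activator of actin-dependent transcription in muscle, by -1.41. In CTR minus VAS, Dpp4, Prss35 and Abra differed by -1.02, -1.17 and -0.79, while AW549542, Mrap2 and Dbp differed by -0.09, 0.88 and 0.17.

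The list of retinoic acid response genes lay inside the random range in VAD with the filter on low values and outside it without. Its 28 members past the filter had a median of -0.06, at the 8.62 percentile of 10000 random lists matched on expression. With no filter the median was -0.13, at the 0.07 percentile. Dhrs3 was the member past 2-fold, and 12 of the 28 were above 0. Rarb, a retinoic acid receptor gene that retinoic acid induces in many tissues, differed by -0.03, and Cyp26b1, which breaks retinoic acid down, by 0.14. Rdh10, which makes retinaldehyde, differed by -0.53, Aldh1a3 by -0.54 (0.20 against CTR), and Hoxa2 by -0.43. A further 9 members lay below the filter on all 4 arrays, among them Cyp26a1 and Stra6. Hox and Tbx patterning genes had a median of -0.15, at the 0.03 percentile, with 5 of 23 above 0 and none past 1.5-fold.

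Smooth muscle contractile genes were slightly higher in VAD as a group. The 41 measured members had a median of 0.14, at the 99.95 percentile, with 35 above 0 and none past 2-fold. Casq2, a calcium-binding protein of the sarcoplasmic reticulum, was 0.78 higher and Ldb3 0.66. Genes of the cytoskeleton and focal adhesions had a median of 0.13, at the 99.8 percentile, with Itgb3 0.90 and Itga5 0.75 higher. Receptors of airway contraction and calcium handling had a median of -0.02, at the 24.5 percentile. Besides Chrm2, Ptger3 differed by -0.78 and Ednrb by -0.60.

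These other lists also lay outside the random range in VAD. Interferon response genes had a median of -0.26, below all 10000 random lists, with 4 of 32 above 0. Ifi27l2a differed by -0.86, Cxcl10 by -0.84 and Igtp by -0.68. Against CTR these 3 differed by 0.26, -0.22 and -0.20, and the list by -0.11. The same list had a median of -0.22 between the controls, at the 0.07 percentile. Heat shock and unfolded protein response genes had a median of 0.24, above all random lists, led by Sdf2l1 with 0.77, which was -0.02 against CTR. They were also 0.19 higher in CTR than in VAS. Glucocorticoid response genes had a median of 0.17, at the 99.4 percentile, with Fkbp5 0.89 and Pdk4 0.89 higher. Lipid uptake and storage genes had a median of 0.18, at the 99.7 percentile. Circadian clock genes had a median of -0.20, at the 0.02 percentile, with Dbp, Hlf at -1.22, Per3 at -1.04 and Nr1d1 among those lower, while Arntl was 1.08 and Npas2 1.16 higher. Mitochondrial oxidative phosphorylation had a median of -0.11, cytosolic ribosomal proteins -0.11, cell cycle genes -0.12 and the xenobiotic and antioxidant response -0.12. All 4 of those lists were lower in CTR than in VAS by more, with medians of -0.27, -0.30, -0.25 and -0.36. Against CTR in place of VAS, the contractile median was 0.21, and those 4 lists changed sign.

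**Figure D1:**
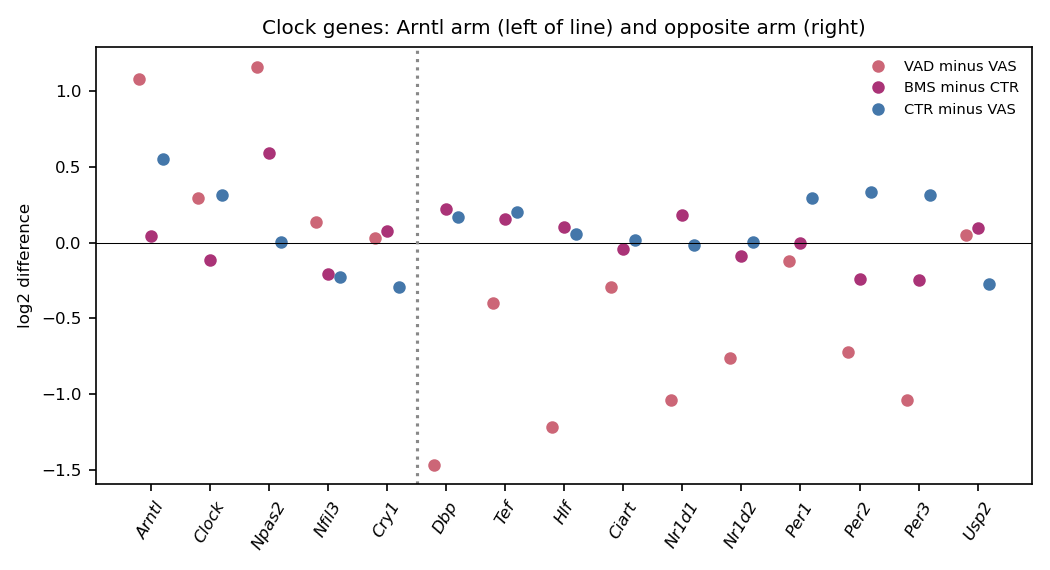
Log2 differences of 15 clock genes in VAD minus VAS, BMS minus CTR and CTR minus VAS (1 array per group), with genes in phase with Arntl left of the dotted line and genes of the opposite phase right of it. In VAD minus VAS, Arntl and Npas2 lie at 1.08 and 1.16 and Dbp and Hlf at -1.47 and -1.22.

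Markers of other cells moved beside these groups. Alveolar epithelial markers had a median of -0.59 in VAD against VAS, below all random lists, and -0.79 in CTR against VAS. Lymphocyte and granulocyte markers had a median of -0.28, at the 0.01 percentile. Against CTR in place of VAS both medians changed sign, to 0.25 and 0.51. Airway epithelial markers had a median of 0.18, at the 99.1 percentile, and -0.0050 with the 75th percentile filter. Fibroblast markers, pericyte markers and macrophage markers lay inside the random range, with medians of -0.02, 0.04 and -0.04. Of the 38 lists, 15 lay outside the middle 95% of random lists, where 1.9 would for lists of independent genes. Genes in a list vary together, so this count says less than it would for independent genes, and between the 2 controls 16 lists lay outside.

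The second comparison asked what blocking the retinoic acid receptors did, BMS against CTR. Il17b was 14.0-fold higher, from 5.89 in CTR to 9.70 in BMS. Angptl1, a secreted angiopoietin-like protein, was 3.35 higher on the log2 scale and Thbs4, a matrix glycoprotein, 3.21. Frzb was 2.91 higher, Itih5 2.89, Sfrp4 2.87, Dkk2 2.37, the matrix protein Cilp 2.49, the homeobox gene Meox1 2.49 and Fap, a fibroblast surface protease, 2.47. In all, 133 genes were at least 2-fold higher and 35 at least 2-fold lower in BMS. Against VAS in place of CTR, 70 were higher and 181 lower, so the balance turns with the control.

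Most of these genes did not stand 2-fold above VAS. Of the 133, 35 also stood 2-fold above VAS, among them Il17b, Angptl1, Thbs4, Cilp, Sfrp4, Dkk2, Fap, Itih5, Meox1 and Frzb. Retnla was 2.53 higher in BMS and Lbp, the lipopolysaccharide binding protein, 2.30. Neither stood 2-fold above VAS, with values of 7.42 against 8.63 and 9.43 against 8.96. Thbs4 was already 2.09 higher in CTR than in VAS. The largest difference downward was H2-T22, a class I histocompatibility gene, with -3.19, followed by the Wnt inhibitor Wif1 with -1.89. H2-T22 lay below the array's median in BMS alone, and the same limit on strain background applies to it. Wif1 stood 2.31 higher in CTR than in VAS, and its BMS value of 8.71 was above the VAS value of 8.29. Cacna1e differed by -1.27, Adhfe1 by -1.26, H4c8 by -1.26, Saa1 by -1.20, Slc22a13b by -1.13 and Rpl6 by -1.13. The T cell receptor joining segments Traj12 and Traj21 differed by -1.46 and -1.35, DQ267101 by -1.22 and AF357426 by -1.15. Of the 35 lower genes, 18 also stood 2-fold below VAS.

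Extracellular matrix genes and fibroblast markers were higher in BMS as groups. Collagens and matrix genes had a median of 0.30, above all 10000 random lists, with 49 of 60 members above 0, 4 of them 2-fold higher and none 1.5-fold lower. Fbln2 was 2.07 higher, Efemp1 1.60 and Col15a1 1.46, while elastin, Eln, differed by -0.55. The list median was 0.05 between the controls, at the 92.3 percentile, and 0.43 in BMS against VAS. Of its members, Fbln2 and Efemp1 were lower in CTR than in VAS by -1.06 and -1.42. Eln was 1.22 higher in CTR than in VAS, so in BMS it stood 0.67 above VAS. Matrix proteases and their inhibitors had a median of 0.22, above all random lists, with Serpinf1 1.99 and the cathepsin gene Ctsk 1.13 higher. Fibroblast markers moved beside them, with a median of 0.30, above all random lists, and 22 of 25 above 0. Cd34 was 1.71 higher, Clec3b 1.51 and Scara5 1.44. The same list was lower in CTR than in VAS, with a median of -0.20 at the 0.455 percentile. Endothelial markers had a median of 0.21, at the 99.9 percentile, and macrophage and monocyte markers 0.19, at the 99.8 percentile. Cholesterol and fatty acid synthesis genes had a median of 0.19, with Scd1 1.15 higher.

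Smooth muscle contractile genes were slightly lower in BMS as a group, opposite to VAD. Their median was -0.13, at the 0.01 percentile, with 6 of 41 above 0 and none past 2-fold. Contractile regulators and transcription factors had a median of -0.09, at the 1.44 percentile. Receptors of airway contraction and calcium handling had a median of -0.12, at the 0.05 percentile. In this list Chrm2 differed by -0.78, while Ptger3 was 1.32 and Avpr1a 1.14 higher. Airway smooth muscle and myofibroblast markers had a median of -0.09, at the 1.89 percentile, and pericyte and vascular smooth muscle markers -0.17, at the 0.06 percentile. Glucocorticoid response genes had a median of -0.13, at the 1.48 percentile, and interferon response genes -0.15, at the 0.11 percentile. Hox and Tbx patterning genes had a median of -0.13, at the 0.56 percentile, with Hoxb4 at -0.83 and Hoxa6 at -0.73. Retinoic acid response genes had a median of 0.06, at the 86.6 percentile. Ret was 1.07 higher, Aldh1a2 0.88, Aldh1a1 0.83 and Meis2 0.81, Rarb differed by 0.16, and Cyp26b1 by 0.12. In BMS, 16 of the 38 lists lay outside the random range. Against VAS in place of CTR, the contractile median kept its sign at -0.11, while contractile regulators (0.04), contraction receptors (0.02), pericyte markers (0.22) and macrophage markers (-0.80) changed sign. The Hox and Tbx median was then -0.001 and that of airway smooth muscle and myofibroblast markers -0.01.

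**Figure D2:**
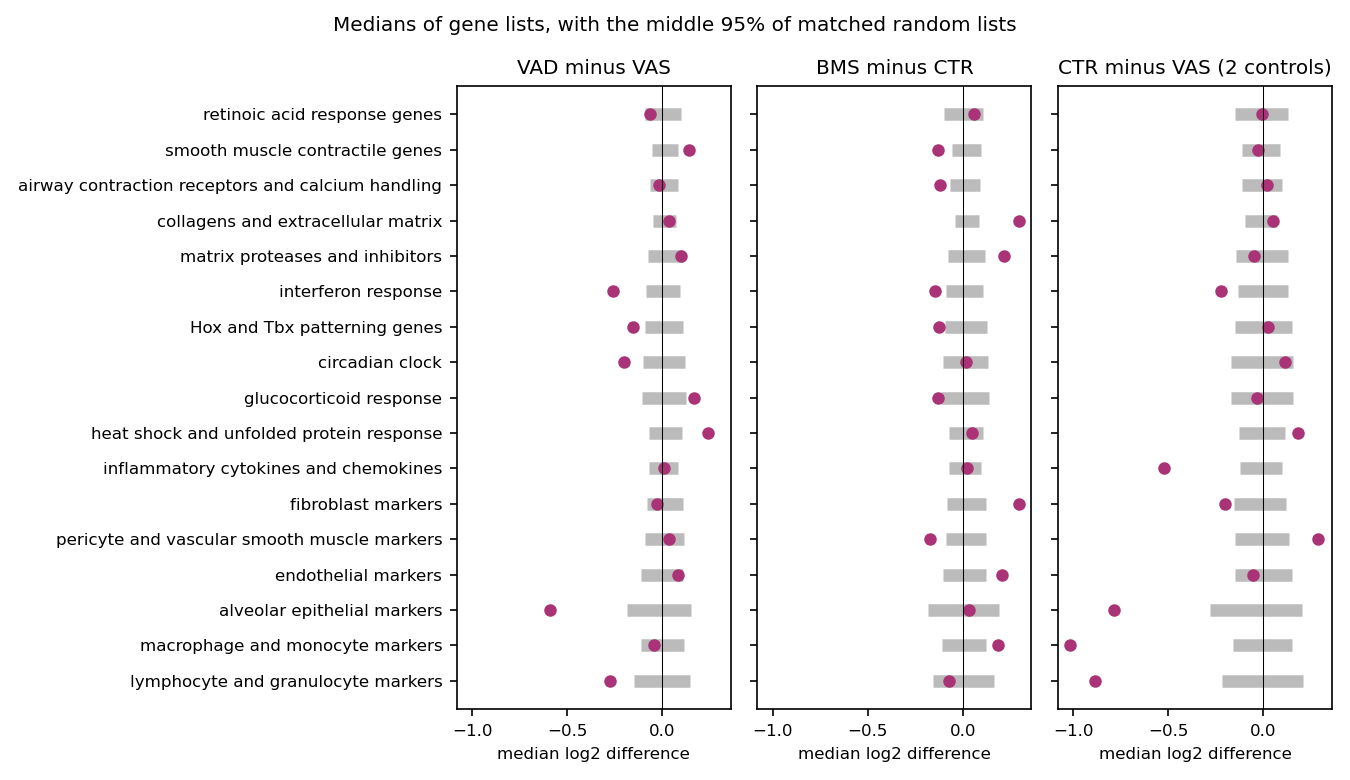
Median log2 difference of 17 gene lists (points) in VAD minus VAS, BMS minus CTR and CTR minus VAS, with the middle 95% of 10000 random lists matched on expression (grey bars), from 1 pooled array per group. Contractile genes lie at 0.14 and -0.13 in the 2 experiments, matrix genes at 0.04 and 0.30, and macrophage markers at -1.01 between the controls.

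The third comparison asked what the 2 experiments shared. Il17b was the gene at least 2-fold higher in both, and Mir505, a microRNA gene named here because the count is so small, the gene at least 2-fold lower in both. Independent lists of these sizes would share 0.311 and 0.147 genes, values that take every gene as equally likely to pass. The genes with the largest same-way differences upward were Il17b, Pdpn with 0.84 and 1.24, Sv2c with 0.75 and 1.09, Aldh1a1 with 0.75 and 0.83, Gas7 with 0.72 and 0.79, Fetub with 0.96 and 0.68, Cmklr1 with 0.65 and 1.44, Mmp3 with 1.09 and 0.63, Casq2 with 0.78 and 0.61, and Npas2 with 1.16 and 0.59, in VAD minus VAS and BMS minus CTR. Pdpn encodes podoplanin, Mmp3 a matrix metalloproteinase and Cmklr1 a chemerin receptor. Downward, Chrm2 differed by -1.25 and -0.78 and Tacr2, the neurokinin A receptor of airway muscle, by -0.72 and -0.75. Others were Hnrnpk with -0.97 and -0.83, Fabp7 with -0.79 and -0.89, Zfp811 with -0.89 and -0.74, Adhfe1 with -0.75 and -1.26, Wif1 with -0.73 and -1.89, and Cfap53, Slc22a13b and Traj18, each between -0.70 and -0.72 in VAD. Not all of these hold against the other control. Fetub (-0.44) and Wif1 (0.42) changed sign in BMS against VAS, and Traj18 (0.07) in VAD against CTR. Aldh1a1 (0.13) and Casq2 (0.19) in BMS, and Hnrnpk (-0.10), Cfap53 (-0.12) and Slc22a13b (-0.03) in VAD, were then within 0.2 of 0.

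**Figure D3:**
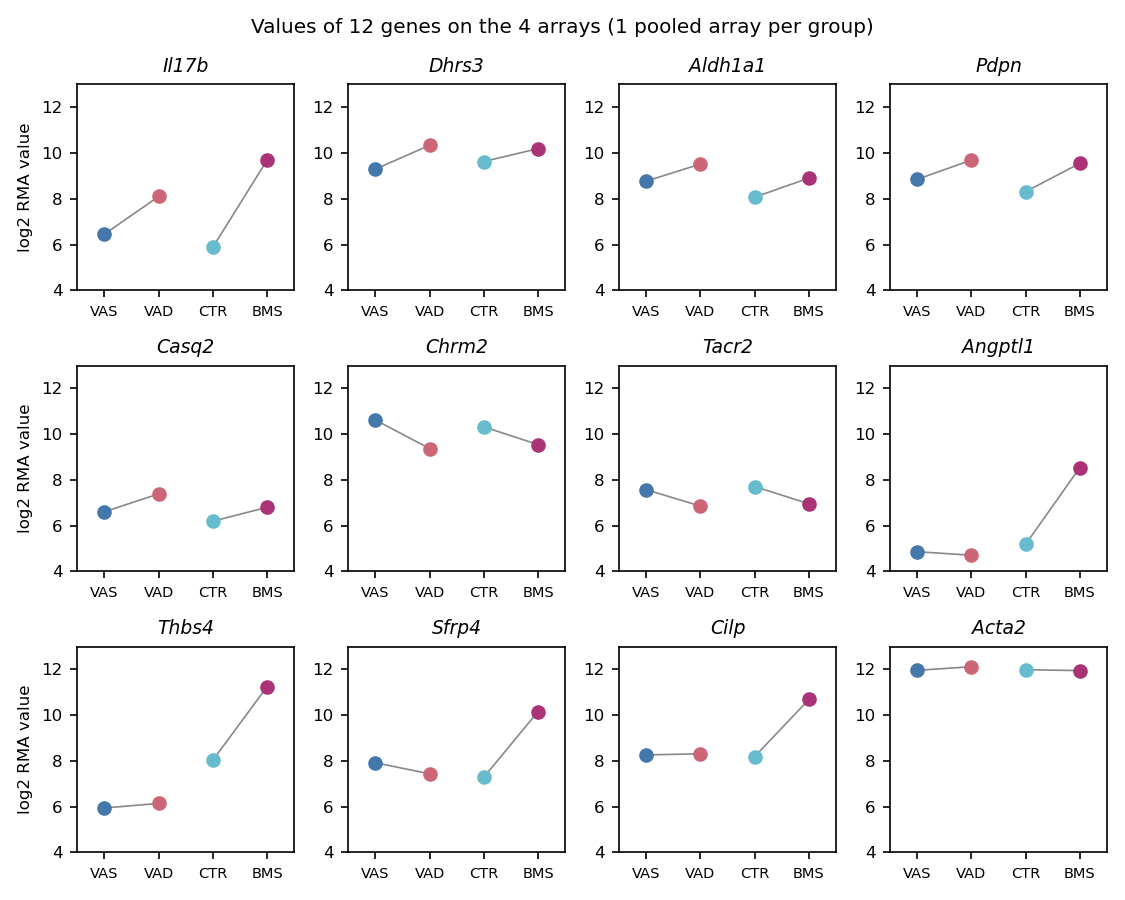
Log2 RMA values of 12 genes on the 4 arrays, 1 point per array of RNA pooled from 3 mice, with lines joining each experiment's control to its VAD or BMS array. Il17b goes from 6.46 to 8.11 and from 5.89 to 9.70, Chrm2 from 10.62 to 9.37 and from 10.32 to 9.54, and Angptl1 is high in BMS alone.

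The 2 experiments also differed in opposite directions. Past 2-fold, 8 genes were lower in VAD and higher in BMS, where independent lists would share 0.558, and none went the other way. This depends on the control: with the mean of both controls, which the experiments then share, 5 genes differed the same way and 4 the opposite way, and outside the range of both controls 2 and 0. With each experiment's control exchanged for the other's, 2 differed the same way and 63 the opposite way. That exchange puts the difference of the controls into both comparisons with opposite signs, so an excess of opposite genes is built in. Across the 12395 genes the 2 differences had a Pearson r of -0.07 and a Spearman rho of -0.04. The experiments have separate controls, so chance differences do not tie them. The 2 other ways of pairing the arrays gave r values of -0.37 (VAD minus CTR with BMS minus VAS) and 0.31 (CTR minus VAS with BMS minus VAD), both further from 0. Both pairings carry the difference between the experiments on each side, with opposite signs in the first and the same sign in the second. At 1.5-fold, 12 genes were higher in both and 25 lower in both, with 5.6 and 4.95 expected, 51 were lower in VAD and higher in BMS, with 8.16 expected, and 13 were higher in VAD and lower in BMS, with 3.4 expected. All 4 counts exceed the value for independent lists, in opposite as in same directions. An excess over that value, at 2-fold too, therefore does not by itself show a shared or an opposed response.

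**Figure D4:**
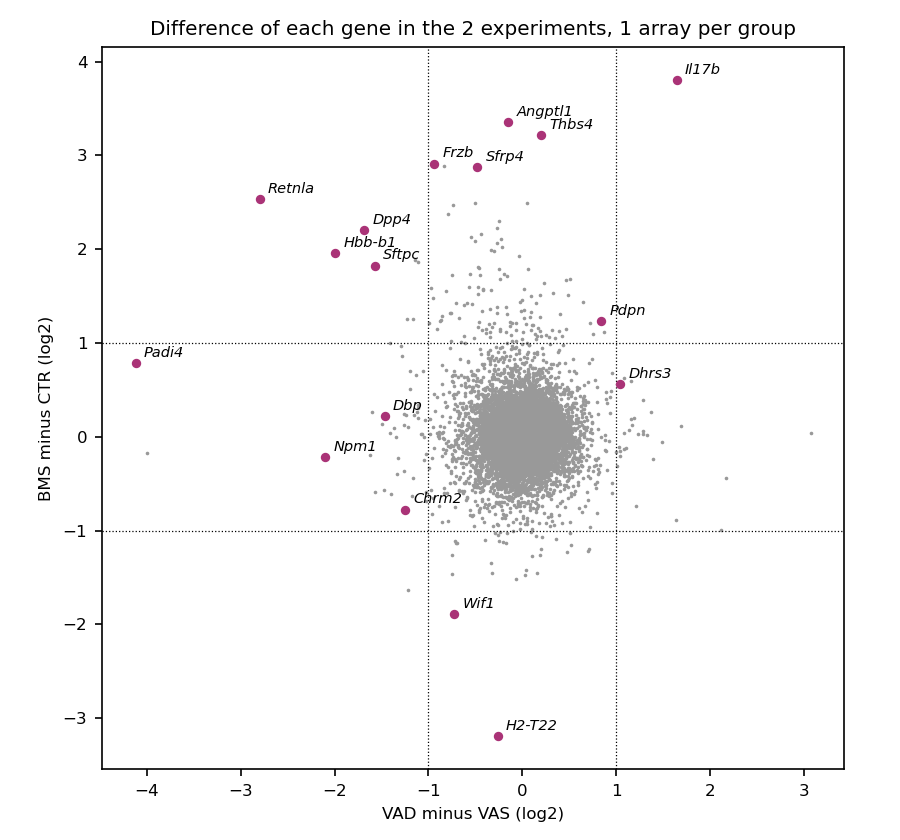
Log2 difference of each of the 12395 genes in VAD minus VAS (horizontal) and BMS minus CTR (vertical), 1 array per group, with dotted lines at 2-fold and some genes of the text labelled. Il17b lies alone at the upper right, and Retnla, Hbb-b1, Dpp4 and Sftpc lie at the upper left.

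Taking VAD and BMS, the deficient diet and the antagonist, together against VAS and CTR, with the experiment as a block, gives the series' only replicated test. No gene passed an adjusted p of 0.05 in limma, and 476 genes had an unadjusted p under 0.05, where 620 would with no change in any gene. This fit has 1 residual degree of freedom, and on simulated data its recovery of 4-fold changes ran from 0 to 50 of 50 depending on the noise assumed, so the count of 0 does not show that no gene changed. By limma's camera, adjusted over the 38 lists, 7 lists passed with a preset correlation of 0.01 and none with an estimated one. With the estimated correlation each of the 7 had an adjusted p = 0.854. That estimate and its test rest on 1 residual degree of freedom, with which a list could hardly pass. None passing therefore does not count against the 7. With the preset correlation, the p-values measure spread across genes and not between pools or mice, so they do not show that a difference would repeat. By this test, collagens and matrix genes were higher in VAD and BMS (adjusted p = 5.87e-07, median 0.21) and interferon response genes lower (adjusted p = 5.87e-07, median -0.19). Hox and Tbx patterning genes were lower (adjusted p = 0.000692, median -0.14), although their median in BMS against VAS was -0.001. Fibroblast markers (adjusted p = 0.00116, median 0.16), endothelial markers (adjusted p = 0.00504, median 0.12), matrix proteases (adjusted p = 0.0183, median 0.15) and cholesterol and fatty acid synthesis (adjusted p = 0.0457, median 0.11) were higher. The matrix gene, fibroblast and cholesterol values rest mainly on BMS, since their medians in VAD were 0.04, -0.02 and -0.004. In VAD, endothelial markers (0.08) and matrix proteases (0.10) also lay inside the random range. Contractile genes (adjusted p = 0.659) and retinoic acid response genes (adjusted p = 0.786) did not pass the preset-correlation test.

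Markers of other cells and other lists differed between the controls. Macrophage and monocyte markers had a median of -1.01 in CTR against VAS, with 12 of 23 at least 2-fold lower, lymphocyte and granulocyte markers -0.88, and inflammatory cytokines and chemokines -0.52, all below every random list. S100a9, a neutrophil gene, differed by -2.74, Ly6c2 by -1.86, Il1b by -1.84 and H2-Ab1 by -1.77. Pericyte and vascular smooth muscle markers were higher in CTR, with a median of 0.29, above all random lists. Contractile genes differed little between the controls, with a median of -0.03 at the 43.7 percentile, and retinoic acid response genes had a median of 0.00 at the 49.8 percentile.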

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

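The results here were picked out by one rule, a difference of opposite sign in the 2 experiments, for lists outside the random range in both or genes past 2-fold in both. With 1 array per group none of these differences between the experiments was tested. Smooth muscle contractile genes had medians of 0.14 in VAD against VAS and -0.13 in BMS against CTR. Glucocorticoid response genes had medians of 0.17 and -0.13. The 8 genes were lower in VAD and higher in BMS. Cadm3 differed by -1.16 and 1.25, Dpp4 by -1.69 and 2.20, Efhd1 by -1.23 and 1.26, and Hbb-b1 by -2.0 and 1.96. Ifi204 differed by -1.15 and 1.89, Ifi211 by -1.11 and 1.86, Retnla by -2.80 and 2.53, and Sftpc by -1.58 and 1.82. Against the other control, Efhd1, Ifi204, Ifi211, Retnla and Sftpc changed sign in both experiments, with 0.12 and -0.089, 1.03 and -0.29, 1.04 and -0.29, 0.94 and -1.21, and 1.96 and -1.71. Hbb-b1 was then -0.072 and 0.030, Cadm3 -0.21 and 0.31, and Dpp4 -0.67 and 1.18. Whether all pools had the same strain background is not given in the sources used here. Of 854 unnamed probe sets, 6 were at least 2-fold apart between VAD and VAS, 12 between BMS and CTR, and 21 between the controls.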

How the results depend on the processing

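Apart from the joint fit, whose experiment block pairs each array with its own control, no paired analysis was possible because the groups share only 1 replicate number. With no replicates, a list median was taken as moved when it shifted by over 0.1 or crossed the random range, and a gene when it shifted by over 1.5-fold. The counts outside the range of both controls and without markers of other cell types were chosen after seeing the data.

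Counts of genes at least 2-fold apart were within 1.5 times of the main ones after quantile normalization, after cyclic loess and with unnamed probe sets. For VAD against VAS, 81 became 143 with no filter, 51 with the 75th percentile filter, 442 at 1.5-fold, 14 at 3-fold, 219 against CTR (174 higher and 45 lower, so the balance turned) and 24 outside the range of both controls. For BMS against CTR, 168 became 94 with the 75th percentile filter, 620 at 1.5-fold, 46 at 3-fold and 53 outside the range of both controls. Against VAS it was 251, with 70 higher and 181 lower, so the balance turned there too. With the mean of both controls, shared by both experiments, the splits were 49 higher and 28 lower for VAD and 69 higher and 49 lower for BMS. For CTR against VAS, 252 became 137 with the 75th percentile filter, 1058 at 1.5-fold and 66 at 3-fold, and stayed close at 219 without markers of other cell types. Genes changed the same way went from 2 to 4 with no filter, 1 with the 75th percentile filter, 37 at 1.5-fold, 1 at 3-fold and 5 with the shared mean control, where part of any excess comes from that control. The correlation of -0.07 became -0.37 with crossed controls, which carry the difference of the controls with opposite signs. The joint limma fit called 0 genes in all 11 alternatives run. Leaving out each array gave 0 to 0, with 171 to 568 genes at an unadjusted p under 0.05. These fits also lack the block, which 3 arrays do not allow, so they differ from the fit on 4 arrays with the block (476) in 2 ways. Splitting the arrays as CTR and BMS against VAS and VAD called 10 genes without the block, against 0 for the real split and 0 for VAD and CTR against the rest, so the experiments are a structure of the arrays. At an unadjusted p under 0.05 these splits gave 1518, 231 and 298 genes, fewer for the real split than for VAD and CTR. The 7 lists called by camera became 0 with an estimated correlation. The retinoic acid response median in VAD became -0.13 with no filter, outside the random range. The cause was not tested for these, apart from the thresholds and filters, which change counts by construction.

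Sign changes of list medians are given here only for medians outside the random range in the main comparison. Against the other control, these medians changed sign in VAD: cell cycle 0.12, oxidative phosphorylation 0.16, ribosomal proteins 0.24, xenobiotic response 0.16, alveolar epithelial 0.25 and lymphocyte markers 0.51. In BMS they were contractile regulators 0.041, contraction receptors 0.021, pericyte 0.22, macrophage -0.80, red blood cell -0.14 and cartilage genes 0.021. With the 75th percentile filter, airway epithelial markers in VAD turned to -0.0050 and cartilage genes in BMS to 0.72. Differences past 2-fold that turned against the other control were, in VAD, Efhd1 0.12, Ifi204 1.03, Ifi211 1.04, Retnla 0.94, Rpl31-ps21 0.19, Sftpc 1.96 and Trim67 -0.0060, and in BMS, Efhd1 -0.089, Ifi204 -0.29, Ifi211 -0.29, Ly6c2 -0.70, Pi16 -0.92, Retnla -1.21, Scd1 -0.27, Sftpc -1.71 and Wif1 0.42. Smaller printed differences that turned were, in VAD, Aldh1a3 0.20, Ifi27l2a 0.26, Sdf2l1 -0.020 and Traj18 0.072, and in BMS, Eln 0.67 and Fetub -0.44. The cause was not tested. Of the 38 lists in both experiments, 75 medians stayed close after cyclic loess. Against the other control 21 stayed close, 43 moved and 12 outside the random range changed sign. Medians inside that range that changed sign were counted as moved or close, such as inflammatory cytokines in BMS (0.02 to -0.53). The named genes give 256 differences, 2 per gene. All 256 stayed close after both normalizations, while against the other control 124 stayed close, 16 past 2-fold changed sign and the rest moved. Signal over background is not known for these arrays, which limits genes near the filter.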

Other observations

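Every test in this part was chosen, and its bounds set, after the values it uses had been seen, and the 3 patterns were picked from 38 lists viewed in 3 comparisons. The genes 2-fold above both controls in BMS included others beyond those named in the report. Ackr4, a scavenging chemokine receptor, stood at 8.80 in BMS against 6.04 in VAS and 6.72 in CTR. Hmcn2, a matrix protein, stood at 9.40 against 7.74 and 7.72, and Epyc, a small proteoglycan, at 7.36 against 5.76 and 5.2. The transporter genes Abca8a, Abca8b and Abca9 were 1.93, 1.64 and 1.20 higher in BMS than in CTR. Musk, a receptor kinase of muscle, was 1.52 higher and the growth factor gene Ptn 1.81. Red blood cell and platelet genes (4 members) had medians of -0.17, 0.35 and -0.93 in VAD minus VAS, BMS minus CTR and CTR minus VAS, and cartilage genes -0.05, -0.24 and 0.11. Nerve and glial genes had medians of -0.04, 0.13 and -0.06, mesothelial markers -0.01, 0.09 and -0.31, cardiac and skeletal muscle genes -0.14, -0.04 and -0.26, and sex-linked genes (3 members) -0.05, -0.24 and 0.25. TGF-beta signalling genes had medians of 0.08, -0.01 and 0.06, Hedgehog, Wnt and Notch genes 0.06, 0.06 and 0.16, insulin-like growth factor genes 0.04, 0.00 and -0.04, glycolysis and hypoxia genes 0.06, 0.06 and -0.11, and immediate early genes 0.07, -0.06 and -0.07.

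The genes at least 2-fold higher in BMS than in CTR form the first pattern. A CTR pool that was low in them may account for part and cannot be told apart from the antagonist, since 26.3% (35 of 133) also stood 2-fold above VAS while 54 of the 133 stood 2-fold lower in CTR than in VAS. Selection by a low CTR value favours low values of the first and high values of the second, and the matching share for genes higher in VAD was 44.8%. More fibroblasts in the BMS pool were weighed for the 98 other genes and for the 35, although the sort is meant to remove fibroblasts too. The test used the 19 of 25 list members under 11 in both controls, which have room for a 2-fold rise. For the 98, their median was 0.35 (SD 0.60), but 5 were 2-fold higher and 22 of all 25 higher, so fibroblasts cannot be told apart from the antagonist. For the 35, their median against VAS was 0.17 (SD 0.47), 17 of all 25 were higher and none 2-fold. The highest was Pdgfra with 0.69, and Pi16 (-0.92), Dpep1 (-0.78), Cxcl14 (-0.66) and Gdf10 (-0.39), named after their values were seen, were lower. Pi16, Dpep1, Cxcl14 and Gdf10 were lower still in CTR, and rose from CTR to BMS by 1.22, 0.61, 0.50 and 0.35. The difference from VAS also holds the difference between the experiments, so it cannot decide on fibroblasts for the 35. More fibroblasts, a fibroblast subset and the antagonist itself stay open. These verdict rules were changed after their outcomes were seen. By 3 earlier fibroblast rules, the quartiles alone excluded fibroblasts for both parts, the quartiles with the count of 2-fold members for the 35, and the count of members higher for neither. For a low CTR pool, the share above VAS alone gave a fit.

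Clock genes between VAD and VAS form the second pattern. The mean of Arntl, Clock, Npas2, Nfil3 and Cry1 and the mean of 10 genes of the opposite phase stood 1.24 apart on the log2 scale, with 5 of 5 and 9 of 10 in the direction of their arm. The arms hold 5 and 10 of the 18 list members past the filter. In BMS minus CTR and CTR minus VAS the arms stood 0.064 and -0.04 apart. Neither of these comparisons holds the VAD array, so they cannot show whether scatter of that single pool accounts for the distance. VAD stood apart for most genes of the opposite phase, with Dbp at 5.84 against 7.31, 7.48 and 7.71 in VAS, CTR and BMS. The Arntl arm was less clear. Npas2 stood at 9.44 in VAD against 8.28, 8.28 and 8.87, and Arntl at 9.59 against 8.51, 9.06 and 9.10. Clock stood at 10.33 against 10.03, 10.34 and 10.23, and Nfil3 and Cry1 differed by only 0.14 and 0.03 between VAD and VAS. Another hour of collection for the VAD mice may account for the distance between the arms. It cannot be told apart from the diet (arms 0.064 apart in the antagonist experiment), because no source used here gives an hour.

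Immune genes that were lower in CTR and BMS than in VAS and VAD form the third pattern. Of the 35 members of the 2 immune lists past the filter, 27 (77.1%) were lower in both, against 21.8% of all genes. Fewer immune cells in the pools of the antagonist experiment may account for this, and the sort on green and not red cells would be meant to remove them. A shift of the scale shared by genes of like expression would move matched random lists too, and these ran from -0.16 to 0.15. The macrophage list had a CTR minus VAS median of -1.01, so such a shift alone does not give its value. The list was picked for this same value, so it is not an independent test. The powdered diet, the vehicle and the pools differ between the experiments together, so a change of expression in the muscle cells was not tested.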
